A study of Arabidopsis thaliana with 9 samples.

How the data were processed

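RNA was sequenced from whole 4-day-old seedlings of 3 genotypes (Col, myb30 and MYB30-OE), with 3 libraries each, from libraries made by standard Illumina protocols, per the labels' protocols. Whether the libraries keep strand is not stated, so sense and antisense transcription at a locus cannot be told apart. The submitters' processing notes name TopHat, Cufflinks, Cuffdiff and the TAIR10 build, with no versions.

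The authors deposited 3 gene tables and 3 transposable element tables, 1 for each pair of genotypes, and a gene annotation. Each table gives a log2 fold change, an average log2 CPM and an unadjusted p-value per feature, per the file headers. These columns are those that edgeR's exact test writes, per the file headers, and not those of Cuffdiff, so which step of the named tools made the counts is not given in the sources used here. The deposited log2 fold change is the second-named genotype over the first, a reading settled by the direction of MYB30. Table names were tied to genotypes through the labels' descriptions of the samples. The authors' deposited annotation gives exon positions (TAIR10) and was used for coordinates, exon lengths and GC content. It holds 28278 of the 33977 gene identifiers of each table, and the TAIR10.1 gene table of the reference holds 32548, which supplied symbols. Of 35176 coding transcripts of the deposited annotation, 99.96% start with ATG in the TAIR10.1 sequence, so positions of both builds were used together. None of 285 organelle gene rows has a read.

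The design fixed before the data were examined called for the authors' adjusted values. These tables hold unadjusted p-values, so Benjamini-Hochberg adjustment was applied here to the deposited p-values, over features with at least 1 read, with a threshold of 0.05. Features without reads, 24.3% to 24.7% of gene rows and 74.6% to 75.3% of element rows, were recognised by the floor of the average log2 CPM and left out. That floor implies the mean library size, on the assumption that the tool's default of 2 reads per library was added. The step from 0 reads to 1 read was 0.116 on the log2 scale, the value for 6 libraries. Implied CPM and reads per genotype were then derived from the average log2 CPM and the fold change, assuming an added count of 0.125 and equal library sizes. They are approximations. Col levels from its 2 tables had a median ratio of 1.02 (central range over genes 1.01 to 1.03) and the cause of the offset was not tested. Sums of 2 deposited log2 fold changes matched the third within 0.0122 for 18345 genes at 1 CPM or more. The median log2 fold change of genes at 1 CPM or more was 0.02 in myb30, 0.00 in MYB30-OE and 0.02 between them. Exact binomial intervals (95%) and floors of 3 reads cover counting error only. Ratios printed with such an interval were taken on implied reads rounded to whole numbers. They can therefore differ from the deposited fold changes given for other features.

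Before the data were examined, 19 gene lists with 290 entries were fixed. They cover light signalling regulators, PIF-induced shade and elongation genes, auxin response genes, brassinosteroid genes, very-long-chain fatty acid and wax genes, salicylic acid and immune genes, reactive oxygen genes, jasmonate genes, light harvesting and Rubisco small subunit genes, chlorophyll synthesis genes, phenylpropanoid and flavonoid genes, glucosinolate genes, circadian clock genes, iron deficiency genes, heat shock genes, seed storage and late embryogenesis genes, root tissue markers, guard cell and phloem companion cell markers, and reference genes. Each list was tested per direction with a one-sided Fisher's exact test of passing members against the other tested genes, with Benjamini-Hochberg adjustment over lists and directions within a comparison. Genes of 1 list are not independent, so these p-values describe the lists in these libraries. Counts adjusted over the list alone used the same p-values. Measured members are those with at least 1 read. LHCB1.5, MYC2 and WSD1 had none in any comparison. Absent reads do not show absent transcripts here, because how the reads were counted is not given. List medians were also ranked among 10000 random lists of the same size matched on level. Overlaps used one-sided Fisher's exact tests.

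The genes named were set by rule. They are MYB30, and per comparison the 10 largest rises and 10 largest falls among passing genes with a mean of at least 1 CPM and at least 1 implied read in the lower genotype. The rule adds the 4 largest passing members of each list, and the 5 largest opposite and 5 largest same-sign changes shared by both lines. Further list members named were chosen after their values were seen. Transposable elements followed the same rule with 3 per direction, of which 2 rises and 2 falls are printed because no names are paired with them.

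Alternatives were an adjusted p of 0.01, a 2-fold change, Bonferroni adjustment, a minimum mean of 1 CPM, no filter, centring on the median, other pseudocounts (0.01, 0.1 and 1) on implied CPM, and a correction for exon length and GC content. The last, the pseudocount of 0.1 and medians with members at their floor were added after the data were seen. The adjustment and list tests were tested on simulated data. Of 100 genes changed by a log2 value of 1, 83% were recovered in myb30 against Col, 86% in MYB30-OE against Col and 93% between the lines. Of 100 changed by 0.5, 38%, 58% and 41% were recovered, and false calls made up 2.4%, 2.7% and 6.3% of calls. Far fewer genes were changed there than passed in the data, which makes the adjusted threshold stricter. The simulated p-values also used the same spread that generated the fold changes. These rates therefore test the working of the adjustment and list tests only, not the deposited p-values or the recovery in the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.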

Results

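Whole seedlings of Arabidopsis thaliana, ecotype Col, were profiled by RNA sequencing after 4 days on MS plates in continuous white light. Wild-type plants (Col), a myb30 mutant and plants overexpressing MYB30 (MYB30-OE) were each represented by 3 libraries, 9 in all. MYB30 is a MYB-family transcription factor known for its part in pathogen-induced cell death and in the synthesis of very-long-chain fatty acids. The series contrasts loss and gain of this factor in light-grown seedlings. The authors deposited the 3 pairwise comparisons for genes and for transposable elements, with a log2 fold change, an average log2 CPM (reads scaled to library size) and a p-value per feature. The tables carry no values of single libraries, so no spread per genotype is given, and each error statement rests on the authors' p-values after Benjamini-Hochberg adjustment. The labels do not say that the libraries of a genotype came from separate cultures, so these p-values measure only the spread between these samples. The tables imply an average of about 33905540 gene reads per library in Col, 36516310 in myb30 and 32367682 in MYB30-OE. Over the 3 libraries of a genotype, 1 read then corresponds to about 0.01 CPM. For transposable elements the implied averages were 292963, 306623 and 275739 reads.

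The MYB30 gene (AT3G28910) lies on the plus strand of chromosome 3 from 10911157 to 10913190 in TAIR10 and has 3 exons. The authors' deposited tables imply 32.2 CPM in Col, 4.55 CPM in myb30 and 617 CPM in MYB30-OE. The transcript was 7.07-fold lower in myb30 than in Col (log2 fold change -2.82, adjusted p = 6.84e-66), so that 14.1% of the Col level was left. In MYB30-OE it was 19.5-fold higher than in Col, with a deposited p-value of 0. The direct comparison of myb30 with MYB30-OE gave a log2 fold change of -7.11, the largest change of any gene at 1 CPM or more in that table. The sign of the deposited fold changes was read from MYB30, so its direction is no test of the labels.

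The comparison of myb30 with Col asks which transcripts differ between the mutant and the wild type in light-grown seedlings. Photosynthesis transcripts fell in the mutant, as did iron-deficiency and wax transcripts, while phenylpropanoid and flavonoid and seed storage transcripts rose. Of 25713 genes with at least 1 read in the authors' deposited table, 5536 passed an adjusted p of 0.05, with 2776 higher and 2760 lower in myb30. Of these, 718 rose and 612 fell by at least 2-fold, 1330 in all, or 479 with a pseudocount of 1 on implied CPM.

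Every measured gene of the light harvesting and Rubisco small subunit list fell in myb30. The deposited table lists 20 of 20 measured members lower (adjusted p = 1.47e-18 by one-sided Fisher's exact test against the other tested genes), and the count was also 20 when adjusted over the list alone. The list median was -0.66, ranging from the light harvesting genes LHCB1.1 and LHCB2.2 (1.35-fold lower each) to LHCB1.4 (2.44-fold lower). The Rubisco small subunit genes RBCS2B and RBCS3B were 1.85-fold and 1.80-fold lower. Copies of LHCB1 and of RBCS are nearly identical in sequence, so the division of reads among them is uncertain. Of 12 chlorophyll synthesis genes 5 fell and 1 rose (adjusted p = 0.0279 for falls), and 8 fell and 1 rose when adjusted over the list alone. The call of that list was lost among genes of at least 1 CPM (adjusted p = 0.0726). CAO, which makes chlorophyll b, was 1.54-fold lower and CRD1 was 1.48-fold lower, whereas PORA, a protochlorophyllide oxidoreductase of etiolated seedlings, was 2.44-fold higher. Markers of other tissues moved in the same libraries. Among 11 root tissue markers 5 rose and 1 fell (adjusted p = 0.0209 for rises), with the same counts when adjusted over the list alone, and the root hair expansin EXPA7 was 2.36-fold higher. The stomatal factor gene FAMA was 1.59-fold lower and the companion-cell sucrose transporter gene SUC2 1.32-fold lower, 2 falls among 3 guard cell and phloem markers (adjusted p = 0.122), as when adjusted over the list alone.

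Iron-deficiency genes showed some of the largest falls in myb30. The authors' deposited table has 5 of 7 measured members lower (adjusted p = 0.0019, list median -3.26, or -1.64 with a pseudocount of 1 on implied CPM), and 5 fell when adjusted over the list alone. These were the bHLH transcription factor genes BHLH100 (31.3-fold lower), BHLH101 (17.3-fold), BHLH38 (log2 fold change -3.33) and BHLH39 (8.42-fold), and IRT1, the root iron transporter gene (9.59-fold). The iron-uptake regulator gene FIT (log2 fold change -0.38) and the ferric reductase gene FRO2 (0.45) did not pass. Very-long-chain fatty acid and wax genes fell as well, with 11 of 24 measured members lower and 2 higher (adjusted p = 1.34e-04, median -0.31), the same counts as when adjusted over the list alone. The elongase genes KCS2 (log2 fold change -1.20) and KCS6 (1.81-fold lower) and the wax genes CER4 (2.21-fold lower) and CER2 (2.06-fold lower) were among them. The exceptions were CER1 (1.41-fold higher) and MYB96, a wax-activating MYB gene (2.02-fold higher).

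Phenylpropanoid and flavonoid genes rose in myb30, 12 of 24 measured against 2 that fell (adjusted p = 2.41e-05, median 0.38), the same counts as when adjusted over the list alone. The anthocyanin-activating MYB genes PAP2 and PAP1 were 5.36-fold and 2.67-fold higher in the authors' deposited table. The late anthocyanin genes DFR and LDOX were 2.21-fold and 2.14-fold higher. MYBL2, a repressor of anthocyanin synthesis, was 2.09-fold lower. CHS, which encodes chalcone synthase, did not pass (log2 fold change 0.18).

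Seed storage and late embryogenesis transcripts rose by far more than those lists. The authors' deposited table has 11 of 14 members higher in myb30 and 1 lower (adjusted p = 1.16e-07), the same counts as when adjusted over the list alone, with a list median of 4.84. The cruciferin gene CRB rose 85.9-fold, from 0.493 to 42.65 CPM, and CRA1 rose 47.1-fold, from 5.05 to 238 CPM. The seed storage albumin genes SESA1 to SESA4, related copies that may share reads, rose 27.4-fold to 65.2-fold. The oleosin genes OLEO1 and OLEO2 rose 31.5-fold and 28.05-fold. The late embryogenesis gene EM6 did not pass (log2 fold change 0.13), EM1 was 3.25-fold higher and the dehydrin gene RAB18 2.28-fold higher. RD29A, a drought-responsive gene, was the member that fell (1.38-fold lower).

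Circadian clock genes were lower in 7 of 16 cases and higher in none in the deposited table of myb30 against Col (adjusted p = 0.0049, median -0.28), and 8 were lower when adjusted over the list alone. RVE1 was 2.13-fold lower, RVE8 1.79-fold, LNK2 1.68-fold and LHY 1.53-fold. Jasmonate genes were mixed, with 6 lower and 3 higher of 18 (adjusted p = 0.0381 for falls), and 7 lower and 3 higher when adjusted over the list alone. VSP1, a vegetative storage protein gene induced by jasmonate, was 3.04-fold lower and JAZ1, a jasmonate repressor gene, 1.34-fold higher. This call was lost among members of at least 1 CPM (adjusted p = 0.13), and the list median of -0.09 lay at percentile 17.5 of random lists matched on level.

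The other lists did not pass in myb30 against Col. Among 30 light signalling regulators in the authors' deposited table, 5 fell and none rose (adjusted p = 0.627), 5 also when adjusted over the list alone. PIF7, a phytochrome-interacting factor gene, was 1.63-fold lower, the blue-light receptor gene CRY1 1.46-fold and PIF5 1.28-fold. PIF4 did not pass (log2 fold change -0.41). Of 20 PIF-induced shade and elongation genes 1 rose and 2 fell (1 and 1 when adjusted over the list alone). Of 16 auxin response genes 2 rose, GH3.1 (1.79-fold) and GH3.3 (1.69-fold), and 2 when adjusted over the list alone. Of 12 brassinosteroid genes 1 rose and 3 fell (1 and 4 when adjusted over the list alone), led by the synthesis gene BR6OX1 (2.19-fold lower). Of 22 salicylic acid and immune genes 2 rose and 2 fell, also when adjusted over the list alone. FRK1 (log2 fold change 2.36) and FMO1 (1.66) rose, and ALD1 (-2.73) and WRKY33 (-0.62) fell. Of 12 reactive oxygen genes 3 rose and 1 fell (4 and 2 when adjusted over the list alone), and ZAT10 was 1.74-fold lower. Of 12 glucosinolate genes 1 rose and 2 fell, also when adjusted over the list alone. Of 3 heat shock genes 1 rose, also when adjusted over the list alone, HSP70 by 1.60-fold. Of 10 reference genes 2 rose, GAPC1 (log2 fold change 0.38) and EF1A (0.31), and 2 rose and 1 fell when adjusted over the list alone.

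Among single genes at a mean of 1 CPM or more, the largest rises in myb30 included genes outside the lists. MEE26, a hydroxyproline-rich glycoprotein gene, rose from 0.0406 to 10.98 CPM in the authors' deposited table (adjusted p = 1.9e-58). AT2G01422, a non-coding RNA gene on chromosome 2 from 183940 to 184734, rose from 0.221 to 32.0 CPM (142.9-fold). The glucosinolate side-chain gene AOP3 rested on about 2 implied reads in Col against 362 in myb30. The ratio of rounded reads was 181, with a 95% exact binomial interval from 49.8 to 1500 for counting error alone. Its deposited log2 fold change was 7.15, against 7.16 for AT2G01422. AT4G30880, a lipid-transfer family gene, had a ratio of 77.3 (interval 26.1 to 377.7) and a deposited log2 fold change of 5.99. PAP85, a cupin-family gene, rose 71.25-fold, the knottin-family gene AT1G47540 63.6-fold and the oleosin gene OLEO4 47.5-fold. Outside the iron list, the largest falls were those of LBD26, a LOB-domain gene (18.6-fold), the defensin-like gene AT1G13609 (16.9-fold), the bHLH-family gene AT5G51790 (10.25-fold), AT1G07367 (8.48-fold) and the thionin gene AT1G66100 (7.76-fold).

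MYB30-OE was compared with Col to ask which transcripts differ in the overexpressor. Light harvesting transcripts and part of the wax and jasmonate transcripts rose, while flavonoid and part of the glucosinolate transcripts fell. Storage protein and oleosin transcripts rose as in the mutant but by less. Of 25593 genes in the authors' deposited table, 2939 passed, with 1533 higher and 1406 lower in MYB30-OE. Of these, 441 rose and 228 fell by at least 2-fold, 669 in all, or 219 with a pseudocount of 1 on implied CPM.

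Very-long-chain fatty acid and wax genes rose in MYB30-OE, 13 of 24 measured against 1 that fell (adjusted p = 1.55e-09, median 0.32), and 15 and 1 when adjusted over the list alone. In the authors' deposited table KCS2 had a log2 fold change of 1.00, KCS6 was 1.75-fold higher and the alkane-forming gene CER1 1.99-fold, while MYB96 fell (log2 fold change -0.59). Light harvesting and Rubisco small subunit genes rose in 17 of 20 cases and fell in none (adjusted p = 2.76e-17, median 0.32), and 19 rose when adjusted over the list alone. LHCB1.4 was 1.48-fold, LHCA1 1.37-fold and RBCS2B 1.36-fold higher. Of 12 chlorophyll synthesis genes 0 passed over all genes and 0 when adjusted over the list alone (median -0.03). Jasmonate genes rose in 8 of 19 cases and fell in none (adjusted p = 5.15e-05), with 8 rises also when adjusted over the list alone. VSP1 had a log2 fold change of 2.81, and LOX4 rose 2.40-fold and JAZ1 2.14-fold. The list median was 0.53, or 0.49 without PDF1.2A, for which no read was implied in Col and too few in MYB30-OE for a bound.

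Phenylpropanoid and flavonoid genes fell in MYB30-OE, 20 of 24 measured against 1 that rose (adjusted p = 1.8e-20, median -0.72), the same counts as when adjusted over the list alone. The flavonol-activating genes MYB11 and MYB111 were 3.09-fold and 2.73-fold lower, PAP1 2.78-fold and CHS 2.01-fold in the authors' deposited table. MYBL2 was the member that rose (1.69-fold). Glucosinolate genes fell in 6 of 12 cases and rose in 1 (adjusted p = 1.19e-04, median -1.21), also when adjusted over the list alone. The median depended on how members were counted. It was -0.50 among members of at least 1 CPM and -0.62 with a pseudocount of 1. The list was split, as CYP79B2, CYP79B3 and CYP83B1 did not pass (log2 fold changes 0.05, 0.11 and -0.075). Falls were not confined to low members, with an average log2 CPM of 3.94 for BCAT4, 4.37 for MAM1 and 4.19 for CYP83A1. The genes that fell were BCAT4 (4.99-fold lower), MAM1 (4.61-fold), CYP83A1 (5.14-fold), CYP79F2 (2.82-fold), the regulator gene MYB28 (1.90-fold) and CYP79F1. No read of CYP79F1 was implied in MYB30-OE against 65.8 in Col, which is at least 22-fold lower against a floor of 3 reads per genotype. MYB51, an activator of indolic glucosinolates, was the member that rose (1.39-fold).

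Iron-deficiency genes rose in MYB30-OE in 3 of 7 cases and fell in none (adjusted p = 0.0297, median 0.62), and 4 rose when adjusted over the list alone. BHLH101 was, per the authors' deposited table, 2.44-fold higher, BHLH100 1.96-fold and BHLH39 1.76-fold, and IRT1 did not pass (log2 fold change -0.41). This call was narrowly lost among members of at least 1 CPM (adjusted p = 0.0502). Seed storage and late embryogenesis genes rose in 12 of 14 cases and fell in none (adjusted p = 2.11e-12, median 2.77), and 13 rose when adjusted over the list alone. CRB rose 17.9-fold and CRA1 8.31-fold, to 41.0 CPM. EM6 rose 3.06-fold and RD29B 3.19-fold. Reactive oxygen genes rose in 5 of 12 cases and fell in 1 (adjusted p = 0.0023), also when adjusted over the list alone, with ZAT10 2.05-fold and the NADPH oxidase gene RBOHD 1.25-fold higher.

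The other lists did not pass Fisher's exact test in MYB30-OE against Col. Their medians were nevertheless extreme among random lists matched on level for root markers (0.34, percentile 99.94), heat shock genes (0.91, percentile 99.89), brassinosteroid genes (0.14, percentile 99.15) and PIF-induced genes (-0.19, percentile 0.62). Among 30 light signalling regulators the authors' deposited table has 2 that rose and 4 that fell (3 and 4 when adjusted over the list alone). PIF4 was 1.42-fold and PIF5 1.17-fold higher, and HYH, a partner of the light-signalling factor HY5, was 1.45-fold lower. Of 20 PIF-induced shade and elongation genes 4 fell and none rose (6 and 1 when adjusted over the list alone, adjusted p = 0.0916 for the list), among them the growth-promoting PRE1 (2.43-fold lower) and the auxin synthesis gene YUC8 (1.55-fold lower). Of 16 auxin response genes 2 fell, also when adjusted over the list alone, with GH3.3 1.92-fold lower. Of 12 brassinosteroid genes 2 rose and 1 fell (3 and 1 when adjusted over the list alone), and the wall-modifying TCH4 was 2.60-fold higher. Of 22 salicylic acid and immune genes WRKY33 rose (2.40-fold) and PR1 fell, and 1 rose and 2 fell when adjusted over the list alone. PR1 had about 2 implied reads in MYB30-OE, a ratio of 12 with an exact interval from 2.98 to 104.8. Of 16 clock genes 3 rose and 3 fell (3 and 4 when adjusted over the list alone), with PRR7 1.48-fold higher. LHY, CCA1 and RVE8 were lower (log2 fold changes -0.48, -0.30 and -0.34). The same 3 genes were lower in myb30 (-0.61, -0.35 and -0.84), so their direction did not follow that of MYB30. Of 11 root markers 3 rose and 1 fell (4 and 1 when adjusted over the list alone, adjusted p = 0.0936 for rises), with the nitrate transporter gene NRT2.1 2.84-fold higher. Of 3 guard cell and phloem markers 1 fell, MYB60 (1.39-fold), and 1 rose and 2 fell when adjusted over the list alone. Of 3 heat shock genes 1 rose, HSP70 (1.88-fold), and 3 when adjusted over the list alone. Of 10 reference genes 1 fell, also when adjusted over the list alone, EF1A by 1.17-fold.

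**Figure D1:**
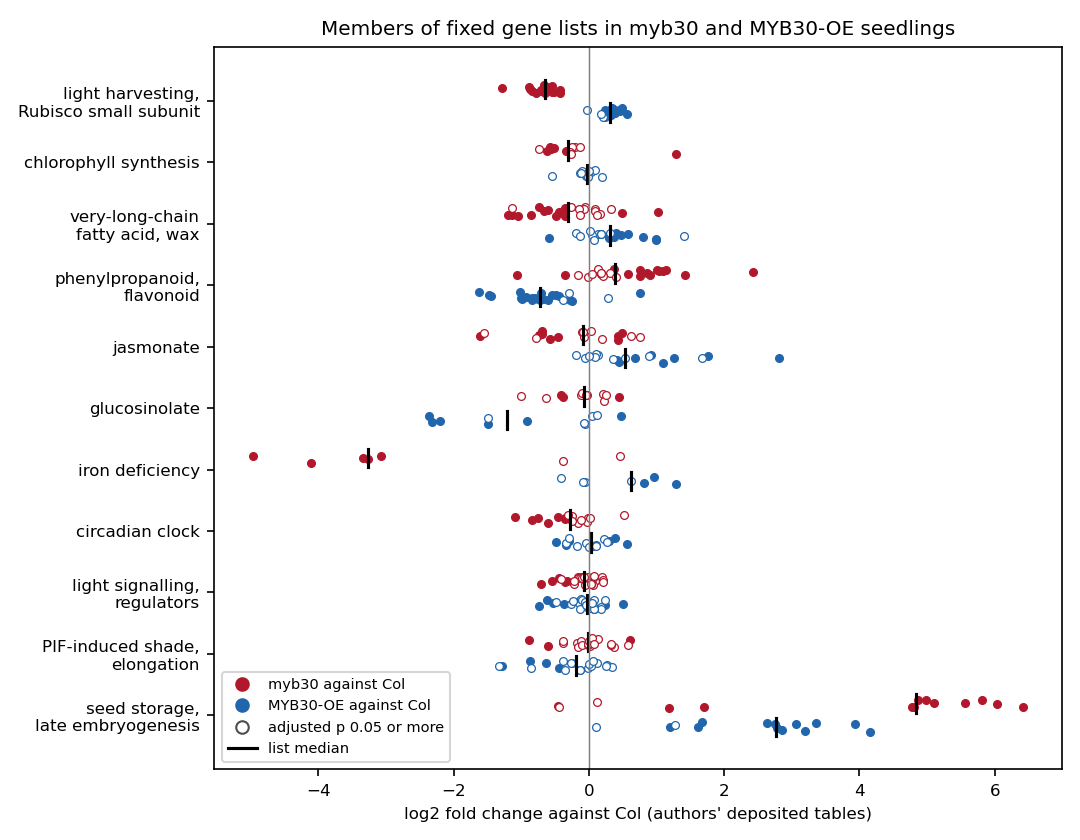
Each point is 1 gene of a fixed list, placed by its log2 fold change against Col in the authors' deposited tables (red, myb30; blue, MYB30-OE). Filled points passed an adjusted p of 0.05, open points did not, black bars are list medians and vertical scatter within a row carries no value. Genes with no implied read in 1 genotype are not drawn but count in the medians. The medians of the light harvesting list lie at -0.66 in myb30 and 0.32 in MYB30-OE, and those of the seed storage list at 4.84 and 2.77.

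Outside the lists, the largest rises in MYB30-OE in the authors' deposited table were those of AT2G01422 (134.9-fold, from 0.214 to 29.4 CPM), AT1G36920 (23.9-fold), QQS, a regulator of starch content (23.7-fold), and the calmodulin-family gene CAM8 (20.2-fold, from 5.55 to 112.0 CPM). The beta-glucosidase gene BGLU24 (12.5-fold), the berberine-bridge-family gene AT1G26380 (12.2-fold) and PAP85 (11.03-fold) followed. The rise of AT1G26380 was far less certain. Its p-value from the authors' pairwise test was 7.92e-04, against 2.79e-37 for BGLU24 and 1.82e-19 for PAP85. Without values of single libraries its spread cannot be examined. The largest falls included those of AT1G29100, a heavy-metal-associated-domain gene (23.1-fold), the endoglucanase-family gene GH9B15 (10.4-fold lower, from 103.6 to 9.94 CPM) and the polygalacturonase genes ADPG1 (8.98-fold) and PGAZAT (6.37-fold). AT5G46950, a pectin methylesterase inhibitor family gene, was 8.74-fold lower. LBD26 was 6.44-fold lower, the cysteine protease gene CP1 6.42-fold, AT1G07690 5.98-fold and the cytochrome P450 gene CYP87A2 5.11-fold.

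Mutant and overexpressor were then set against each other. Among 25054 genes tested in both comparisons with Col, 891 passed in both with opposite signs and 392 passed in both with the same sign. Genes down in myb30 and up in MYB30-OE numbered 540, where independent lists of those sizes would share 168.2 (one-sided Fisher's exact test, p = 2.33e-152). Genes up in myb30 and down in MYB30-OE numbered 351 against 154.9 (one-sided Fisher's exact test, p = 2.1e-52). By the same one-sided Fisher's exact test, genes up in both numbered 239 against 168.2 (p = 8.04e-09), and genes down in both 153 against 154.9 (p = 0.579). Among genes that also changed by at least 2-fold in both lines the order was turned, with 142 of the same sign and 79 of opposite sign. The 2 comparisons share the Col libraries, which alone pull them toward the same sign. Across 18395 genes at 1 CPM or more the correlation of the deposited log2 fold changes was 0.05, and genes are not independent replicates. Simulated unchanged genotypes against shared controls gave 0.50, a value set by the sharing itself. Real changes widen both sets of fold changes and would lower the correlation even if unrelated. The gap between 0.05 and 0.50 therefore does not measure opposing effects. The covariance was 0.0078 against a simulated 0.0151 (range 0.0143 to 0.0159 over 100 draws), a difference of -0.0072. The Col libraries could not be split to remove the sharing.

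**Figure D2:**
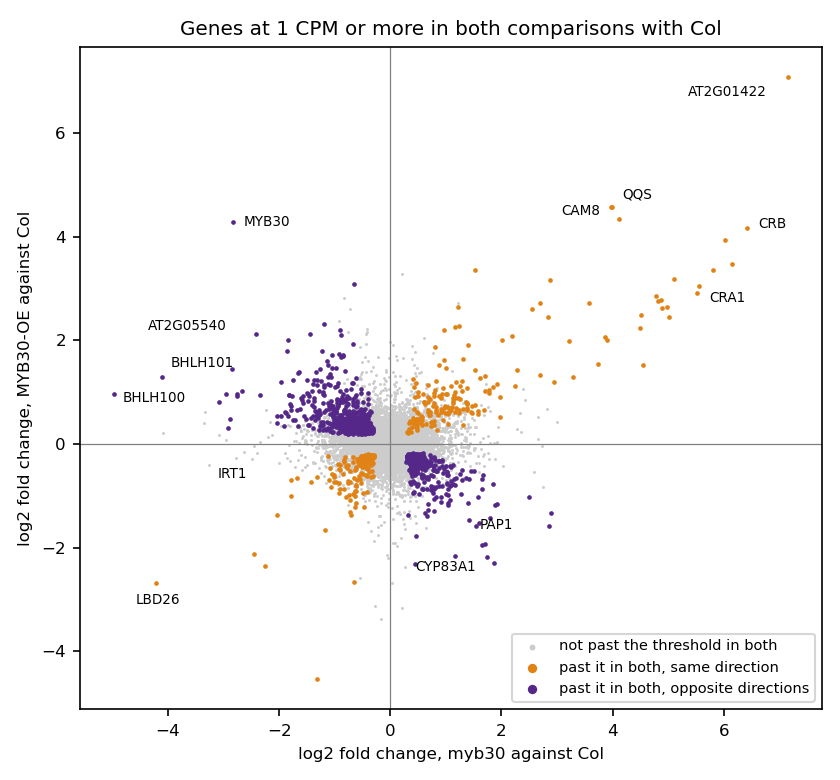
Each point is 1 gene at 1 CPM or more in both comparisons, placed by its deposited log2 fold change in myb30 against Col (horizontal axis) and in MYB30-OE against Col (vertical axis). Genes past an adjusted p of 0.05 in both are purple where the signs are opposite and orange where they are the same. MYB30 lies at -2.82 and 4.28, and the orange points at the upper right include CRB at 6.42 and 4.16.

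After MYB30, the largest opposite changes in the authors' deposited tables were those of 2 iron regulators and 2 other genes. BHLH100 was 31.3-fold lower in myb30 and 1.96-fold higher in MYB30-OE, and BHLH101 17.3-fold lower and 2.44-fold higher. AT2G05540, a glycine-rich protein gene, was 5.32-fold lower in myb30 and 4.32-fold higher in MYB30-OE. BARS1, a triterpene synthase gene, was 7.21-fold higher in myb30 and 2.99-fold lower in MYB30-OE. The genes with the largest changes of the same sign were AT2G01422 and the seed genes CRB, SESA2, PAP85 and SESA1. AT2G01422 did not differ detectably between both lines (log2 fold change 0.08, adjusted p = 0.685), whereas CRB, SESA2, PAP85 and SESA1 were 4.79-fold, 4.25-fold, 6.45-fold and 5.46-fold higher in myb30 than in MYB30-OE.

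In the direct comparison, 8092 of 25647 genes passed in the authors' deposited table, 4151 higher and 3941 lower in myb30 than in MYB30-OE. All 20 light harvesting and Rubisco small subunit genes were lower in myb30 (adjusted p = 1.97e-15, median -0.96), as when adjusted over the list alone. Flavonoid genes were higher in 21 of 24 cases and lower in 1 (adjusted p = 5.5e-13, median 1.19), as when adjusted over the list alone, with PAP1 7.39-fold, PAP2 6.45-fold and 5MAT 3.79-fold higher. Wax genes were lower in 18 of 24 cases and higher in 2 (adjusted p = 1.47e-09), and lower in 19 when adjusted over the list alone, with KCS2 4.60-fold lower. Jasmonate genes were lower in 11 of 19 cases and higher in none (adjusted p = 2.4e-04), as when adjusted over the list alone, led by VSP1 (21.3-fold lower) and JAZ7 (9.99-fold lower). Iron-deficiency genes were lower in 5 of 7 cases (adjusted p = 0.0065), as when adjusted over the list alone, with BHLH100 61.3-fold lower. Clock genes were lower in 9 of 16 cases and higher in 1 (adjusted p = 0.0012), as when adjusted over the list alone. Brassinosteroid genes were lower in 6 of 12 and higher in 2 (adjusted p = 0.0221, median -0.34), and lower in 7 and higher in 2 when adjusted over the list alone. That call was lost among members of at least 1 CPM (adjusted p = 0.0641). Glucosinolate genes were higher in 7 of 12 cases and lower in 2 (adjusted p = 0.0058), as when adjusted over the list alone, and seed storage and late embryogenesis genes higher in 9 of 14 and lower in 3 (adjusted p = 5.26e-04), as when adjusted over the list alone.

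The remaining lists did not pass between myb30 and MYB30-OE. Of 30 light signalling regulators 4 were higher and 7 lower in myb30 in the authors' deposited table, as when adjusted over the list alone, with PIF4 1.88-fold and PIF5 1.51-fold lower. Of 20 PIF-induced genes 6 were higher and 1 lower, as when adjusted over the list alone (adjusted p = 0.313), with PRE1 3.05-fold and YUC8 higher (log2 fold change 1.00). Of 16 auxin genes 3 were higher, as when adjusted over the list alone, led by GH3.3 (3.25-fold). Salicylic acid and immune genes numbered 3 higher and 2 lower of 22, as when adjusted over the list alone, with WRKY33 3.69-fold lower and FMO1 5.73-fold higher. PR1 had a ratio of 26.5 (exact interval 6.98 to 224.5) and PR2 was at least 4.33-fold higher in myb30, with no read implied in MYB30-OE. Reactive oxygen genes numbered 3 higher and 3 lower of 12 (3 and 5 when adjusted over the list alone). Chlorophyll synthesis genes numbered 1 higher and 4 lower of 12 (1 and 5 when adjusted over the list alone), root markers 2 higher and 1 lower of 11, and guard cell and phloem markers 2 lower of 3, the last 2 lists also when adjusted over the list alone. No heat shock gene of 3 passed, over all genes or when adjusted over the list alone. Reference genes numbered 3 higher and 1 lower of 10, also when adjusted over the list alone, with ACT2 1.33-fold lower and GAPC1 1.45-fold higher.

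Outside the lists, the genes highest in myb30 relative to MYB30-OE in the authors' deposited table included ADH1, the alcohol dehydrogenase gene (18.5-fold, from 12.4 to 229 CPM), and BARS1 (21.5-fold). The peroxidase-family gene AT5G19890 (18.0-fold), the GDSL lipase-family gene AT5G08460 (27.2-fold) and AT1G75945 (49.8-fold) were also among them. AT4G30880 had a ratio of 115 with about 2 implied reads in MYB30-OE (exact interval 31.5 to 955.3). AT2G17850, FOLB3, AT3G29970 and AT1G12805 were 15.1-fold, 12.5-fold, 12.1-fold and 11.9-fold higher. Those lowest in myb30, after MYB30, the bHLH genes and VSP1, were AT2G05540 (23.0-fold), BT1, a BTB and TAZ domain gene (19.6-fold), AT1G13609 (19.6-fold) and AT1G66100 (15.2-fold).

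Of 7919 transposable elements with at least 1 read in the authors' deposited table of myb30 against Col, 173 passed, with 99 higher and 74 lower. In MYB30-OE against Col 64 of 7744 passed, with 37 higher and 27 lower, and between the lines 326 of 7695 passed. Among elements with a mean of at least 1 read per library the counts were 247, 94 and 408. Of 23 elements that passed in both comparisons with Col, 15 had the same sign and 8 opposite signs. AT3TE58655 had about 2 implied reads in Col, 604 in myb30 and 737 in MYB30-OE, ratios of 302 (exact interval 83.2 to 2499) and 368.5 (interval 101.7 to 3049). Its deposited log2 fold changes were 7.95 in myb30 and 8.34 in MYB30-OE. AT4TE06710 rose 80.6-fold in myb30 and 16.8-fold in MYB30-OE from about 4 implied reads in Col. AT3TE43080 was 17.4-fold lower in myb30 and 12.2-fold lower in MYB30-OE, and AT5TE46175 17.1-fold and 3.11-fold lower. The files do not pair these identifiers with names or positions. Reads of elements inside or beside genes cannot be separated from gene transcription in these tables.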

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

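The list correction for exon length and GC content, the pseudocount of 0.1 and medians with members at their floor were chosen after the results were seen, and the other settings were planned. The calls of 26 list results were tested again among genes with a mean of at least 1 CPM, where 22 were kept and 4 lost. The pseudocount, centring and length and GC settings move medians but test no call, and 0 of their 75 medians reversed sign. The jasmonate list has no length and GC median in any comparison. Whether its median of -0.0941 in myb30 keeps its sign under that correction is therefore not known. The lost calls were jasmonate genes in myb30 (median -0.0941, adjusted p = 0.13), chlorophyll synthesis genes in myb30 (median -0.31, adjusted p = 0.0726), iron-deficiency genes in MYB30-OE (median 0.62, adjusted p = 0.0502) and brassinosteroid genes between the lines (median -0.34, adjusted p = 0.0641). These 4 medians did not move. Passing members left only the jasmonate list, where falls went from 6 to 5, so the other 3 calls changed through the genes compared against. Some medians that kept their call shrank. That of glucosinolate genes in MYB30-OE went from -1.21 to -0.50 among members of at least 1 CPM, -0.53 with the length and GC correction, which also leaves out genes under 1 CPM, and -0.62 with a pseudocount of 1, and between the lines from 0.69 to 0.40 among members of at least 1 CPM and 0.36 with a pseudocount of 1. With a pseudocount of 1, iron-deficiency genes went from -3.26 to -1.64 in myb30 and from -3.89 to -2.12 between the lines, and in myb30 wax genes from -0.31 to -0.21 and root markers from 0.36 to 0.24. Counts of passing genes fell under stricter settings, as those are built to do. For myb30 against Col they were 3561 at an adjusted p of 0.01, 1330 with a 2-fold change and 1306 with Bonferroni adjustment. For MYB30-OE against Col they were 1876, 669 and 752. Between the lines they were 2157 with a 2-fold change and 2551 with Bonferroni adjustment. For elements the Bonferroni counts were 74 in myb30, 24 in MYB30-OE and 138 between the lines. In MYB30-OE 33 elements passed at 0.01, 38 with a 2-fold change and 34 with no filter on reads, and 182 passed with a 2-fold change between the lines. With a mean of at least 1 read per library, element counts rose to 247 in myb30, 94 in MYB30-OE and 408 between the lines. Of genes shared by both lines, 199 had the same sign and 492 opposite signs at an adjusted p of 0.01, but 142 the same sign and 79 opposite signs with a 2-fold change in both. The cause was not tested. Read from the other table that holds each genotype, MYB30 was at 31.7 CPM in Col, 4.55 in myb30 and 626.7 in MYB30-OE. With a pseudocount of 1 on implied CPM, 2-fold changes among passing genes numbered 479 in myb30, 219 in MYB30-OE and 976 between the lines.

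No paired analysis was possible because the tables hold no values of single libraries. For the same reason leaving out each replicate in turn, DESeq2, the replicate block and other splits of the samples were not run. In the simulated data, changes of 0.5 on the log2 scale were recovered in 38% of cases for myb30 against Col. That rate does not carry over to the data, where far more genes passed. Elements had 275739 to 306623 implied reads per library.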

Other observations

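The gene families and the tests of patterns below were all chosen after the results were seen. Ribosomal protein genes formed the largest coordinated group outside the fixed lists, as far as 22 families picked by product name show. Of 379 measured in the authors' deposited table, 237 were higher and 30 lower in myb30 than in Col (adjusted p = 5.28e-125, one-sided Fisher's exact test adjusted over families, comparisons and directions). In MYB30-OE 116 of 376 were lower and 3 higher (adjusted p = 8.04e-51). Photosystem and light harvesting genes went the other way, with 47 of 54 lower and none higher in myb30 (adjusted p = 6.01e-36) and 26 higher and 1 lower in MYB30-OE (adjusted p = 5.52e-16). Proteasome subunit genes were higher in myb30 than in MYB30-OE in 20 of 45 cases and lower in 1 (adjusted p = 1.58e-04).

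Defence and cell wall families also moved, and those detailed here are a selection. Late embryogenesis abundant, oleosin, xyloglucan enzyme, peroxidase, aquaporin, GDSL lipase, WRKY and glutathione S-transferase genes also passed in a comparison with Col. Peroxidase genes passed in both directions in MYB30-OE, with 14 higher and 17 lower of 97. NBS-type disease resistance genes fell in myb30 in 37 of 127 cases and rose in 5 (adjusted p = 5.84e-07). In MYB30-OE 15 rose and none fell, which did not pass (adjusted p = 0.0541). Lipid transfer protein genes fell in myb30 in 26 of 90 cases and rose in 13 (adjusted p = 4.91e-05), while in MYB30-OE 14 of 87 rose and 5 fell (adjusted p = 0.0056). In myb30 arabinogalactan protein genes fell in 15 of 51 and rose in 4 (adjusted p = 0.0022). Proline-rich cell wall protein genes rose in MYB30-OE in 37 of 186 cases and fell in 8 (adjusted p = 1.1e-08), and in myb30 38 rose and 28 fell (adjusted p = 0.0018 for rises). Expansin genes fell in MYB30-OE in 9 of 26 cases and rose in 3 (adjusted p = 9.96e-05), and cytochrome P450 genes rose in that line in 32 of 219 and fell in 15 (adjusted p = 1.02e-04). In myb30 37 of 223 P450 genes fell and 27 rose (adjusted p = 0.0394 for falls).

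The tests in the next paragraphs were likewise chosen after the results were seen, and some were changed after their own values were seen. The test of a single seed source was first run over all 10 list members that rose in both lines. The rise in MYB30-OE divided by the rise in myb30 then varied 6.36-fold, past the limit of 4 set for rejecting that source. RAB18 was split off only after this value was seen. A test of MYB30 level acting in 1 direction on the seed list was also run and left out, its value being the list median of 2.77 in MYB30-OE, the same sign as in myb30. Tests run on the genes high in both lines were left out too, because 2 of the 3 outcomes did not depend on the values, and only the counts are given.

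Seed storage transcripts were higher than Col in both lines although MYB30 moved in opposite directions. Low Col libraries alone would leave both lines alike, but the comparison that leaves Col out had a list median of 1.99. A single source of seed RNA in different amounts, such as late-germinating seeds, may explain the 9 storage protein and oleosin genes. Their ratio of rises varied 1.54-fold (0.155 to 0.239). Such a source does not explain all 10 (6.36-fold), as RAB18 had a ratio of 0.985 and EM6 and RD29B rose only in MYB30-OE. A shared regulator of seed genes would give the same near-constant ratio. Late embryogenesis abundant genes, a family picked by product name, also rose in both lines. In myb30 21 of 77 rose and 6 fell, and in MYB30-OE 17 of 75 rose and 1 fell. Between the lines 17 of 78 were higher and 16 lower in myb30 (median 0.09 at 1 CPM or more). That family as a whole therefore lacked the larger rise in myb30 seen for the 9 genes. The 35 other genes at least 8-fold higher in myb30 had a median ratio of 0.158 (quartiles 0.107 to 0.316). Outside the list, the seed gene PAP85 (ratio 0.137) and the oleosin-family gene AT3G01570 (0.138) rose that far too. These 35 genes are therefore not a comparison free of seed genes. A general delay would lower light harvesting transcripts, whose median was -0.66 in myb30, in line with a delay there, and 0.32 in MYB30-OE, against one unless excess MYB30 itself raises those genes. Germination and stage are not given in the labels and remain open.

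The opposite movement of ribosomal protein and photosystem genes in myb30 was weighed against gene features, the medians of both families differing by 1.01 on the log2 scale before correction. The difference was 1.02 after a correction for exon length and GC content and 0.998 after one for expression level, so neither trend could account for it as the whole cause. The ribosomal protein and photosystem families were close in median exon length (827.5 and 996 bases) and median GC content (42.3% and 44.0%). The length and GC correction therefore had little room to move the difference. Both families moved the other way in MYB30-OE (medians -0.17 and 0.21), and whether they depend on MYB30 level was not tested. Differences in growth stage, tissue proportions or harvest between the genotypes were not tested and remain open. The root tissue marker list had medians of 0.36 in myb30, 0.34 in MYB30-OE and 0.02 between the lines. Each of these medians was the value of PLT1, which did not pass in any comparison. Other members went both ways between the lines, with 2 higher and 1 lower in myb30, among them WOX5 (log2 fold change 0.94) and NRT2.1 (-1.81). These medians therefore do not decide whether tissue proportions differed.

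A set of 28 genes at 1 CPM or more was at least 4-fold higher than Col in both lines. Of these, 18 were higher in myb30 than in MYB30-OE by the authors' direct comparison, 2 were lower and 8 did not pass. Those 8 included AT2G01422 and CAM8, which rose from 5.68 CPM in Col to 98.7 in myb30 and 112.0 in MYB30-OE. QQS, 1 of the 2 lower genes, rose from 0.385 CPM to 6.16 and 8.79. Genes at least 4-fold lower in both lines numbered 3, LBD26, CYP87A2 and AT3G25150, the last named after its values were seen. The labels do not give the parent seed stock of either line.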
